A study of Mus musculus with 33 samples.

How the data were processed

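Libraries were made on a droplet platform with 5' V(D)J amplification, per the labels' protocols. Cell Ranger and the builds GRCm38 and mm10 are named in the submitters' processing notes; the tools for germline alignment and clone assignment are not given in the sources used here. The authors deposited a combined table of 52509 productive heavy chains, 1 per cell barcode and sample. It holds UMI counts and read counts per heavy chain, and V and J identity to germline as a fraction, per the file headers. It also names the V, J and constant gene, the junction and the authors' clone. No constant gene was given for 230 cells (0.438%), which stayed out of isotype shares, and 0 cells were IGHE. Light chains were not analysed here. No doublets were called here, since the table holds 1 heavy chain per cell, and whether they were removed earlier is not given in the sources used here.

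Samples were grouped by tissue and age in their labels, and mice were the replicates. The mouse names in the table pair the samples across tissues, and on this ground the numbers were taken to pair them. As a check, identical heavy chains were more frequent in own blood than in blood of other mice of that age in 10 of 13 mice (mean 4.49% against 0.391% of dura cells, sign-flip permutation p = 0.00195). This came from aged mice, with 7 of 7 (8.03% against 0.642%, exact sign-flip permutation p = 0.0156). In young mice alone it held in 3 of 6 (0.359% against 0.0986%, exact sign-flip permutation p = 0.25), so their pairing rests on the names. Mice numbered 1 to 3 and 4 to 7 were treated as the 2 sequencing batches the design text describes, which is an inference: the labels hold 1 young dura sample more than that text, from young mouse 5, which has no blood sample here.

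A clone was the authors' clone name within a mouse, since 54 names recurred in over 1 mouse; 145 identical heavy chains within mice were divided over several names. Isotype shares and mutation used samples of at least 20 cells. The share of cells in clones of 2 or more used samples of at least 100 cells, thinned to 119 cells (mean of 200 draws), which left out 2 samples. V mutation was the mean percent of V bases differing from germline, and 94.2% of cells had none. CDR3 length and gene lists were taken over clones. The lists were IGHV2 with IGHV5, IGHV1 with IGHV8, the B-1-associated genes (IGHV11-1, IGHV11-2, IGHV12-3, IGHV6-6, IGHV1-55 and IGHV7-1), and IGHJ1, IGHJ2, IGHJ3 and IGHJ4 each.

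Values per sample were compared by two-sided exact permutation of the difference in means in 7 comparisons, with Benjamini-Hochberg adjustment over 32 tests of main measures, 28 of isotype classes and 49 of gene lists. Comparisons between tissues permuted samples freely, although the tissues came from the same mice. The mouse as a block was an alternative only. There 6 young dura and blood pairs allow no exact sign-flip p under 0.0312, and 7 aged pairs none under 0.0156. The plan had adjusted isotype classes together with the main measures; over these 60 tests jointly, 0 calls changed and the largest adjusted p among the 22 calls was 0.0318. Clones per V gene were tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, all 6 groups in 1 fit), which kept 39 of 99 V genes. The test was checked on simulated counts with 8 changed genes, balanced in direction, in each of 20 simulations. It recovered 73.8% of 2-fold and 95% of 4-fold changes between dura ages, 100% and 100% between blood ages, 13.8% and 60% between bone marrow ages, 78.8% and 100% between young dura and blood, and 87.5% and 100% between aged dura and blood.

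The V genes named were up to 10 with the largest positive and negative fold changes among those with an adjusted p under 0.05, the 4 with the smallest p where fewer than 4 passed, and tested B-1-associated genes. Constant genes and any sample's largest clone above 5% of cells could be named too. Groups, tests, lists, this rule and most alternatives were set before the data were examined; the emphasis on IgD, 6 alternatives and all tests of explanations came after. Positions of the 99 V genes were matched by symbol to a GRCm38 gene table. Alternatives were leaving out each sample, the mouse as a block, the 2 sets of numbers, a minimum of 3 UMIs, other clone definitions and depths, other cell subsets, DESeq2 1.42.0, library sizes alone and no filter on low counts. Analyses used Python 3.11.15, scipy 1.17.1 and R 4.3.3.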

Results

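Heavy chain sequences of single B cells were read from the dura, the peripheral blood and the tibial bone marrow of young and aged C57BL/6 mice. The dura is the outermost membrane around the brain. The 33 samples came from 14 mice and held 52509 cells with a productive heavy chain, which the authors had assigned to 49540 clones. Dura was sampled from 7 young and 7 aged mice, blood from 6 young and 7 aged mice, and bone marrow from 3 mice of each age. Young dura samples held 119 to 753 cells and 732 to 4215 heavy chain molecules counted by unique molecular identifiers (UMIs), and aged dura samples 90 to 907 cells and 785 to 51050 UMIs. Young blood samples held 1913 to 6837 cells and 13100 to 179138 UMIs, and aged blood samples 1284 to 4314 cells and 21121 to 64892 UMIs. Bone marrow samples held 73 to 352 cells in young and 150 to 486 cells in aged mice. The median heavy chain had 5 UMIs in young dura, 4 in aged dura, 5 in blood of either age, 2 in young and 3 in aged bone marrow. Intervals given for single samples cover counting error only, and all tests were two-sided.

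The first comparison set dura against blood. IgD, which mature naive B cells carry beside IgM, was assigned to 5.51% ± 2.06 (SD, n = 7) of young dura cells and 24.4% ± 5.32 (SD, n = 6) of young blood cells, and all 7 dura samples lay below every blood sample. In aged mice IgD made up 4.41% ± 1.98 (SD, n = 7) of dura cells and 18.8% ± 7.62 (SD, n = 7) of blood cells. IgM, like IgD a class of cells that have not switched, took 93.5% ± 2.65 of young dura cells and 74.3% ± 5.13 of young blood cells (exact permutation p = 0.000583, adjusted p = 0.00816), a difference of 19.2 percentage points, or 11.9 with at least 3 UMIs. Each cell was given 1 class and few were switched, so the IgM difference mirrors that of IgD and is no separate result. The IgD difference was -18.9 percentage points in young mice (exact permutation p = 0.000583, adjusted p = 0.00816) and -14.4 in aged mice (exact permutation p = 0.00408, adjusted p = 0.0179). Aged blood of mouse 2 held 3.27% IgD, so that 1 of 7 aged dura samples lay below every aged blood sample. In young mice the IgD difference was -17.4 percentage points in the mice numbered 1 to 3 and -20.2 in those numbered 4 to 7, and in aged mice it was -9.27 and -18.2. The difference depended on heavy chain depth. With at least 3 UMIs per heavy chain it was -11.4 in young and -9.48 in aged mice. With 5 or more it was -5.71 (exact permutation p = 0.00291) and -4.29 (exact permutation p = 0.00175). IgD itself became rare with depth in both tissues. In young mice it was 58.6% of blood and 28.7% of dura cells at 1 UMI, and 1.99% and 0.372% at 9 or more. In aged mice it was 63% and 20%, and 1.03% and 0.303%. IgD as the lead of this comparison and the setting with 5 or more UMIs were chosen after the data were seen.

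**Figure D1:**
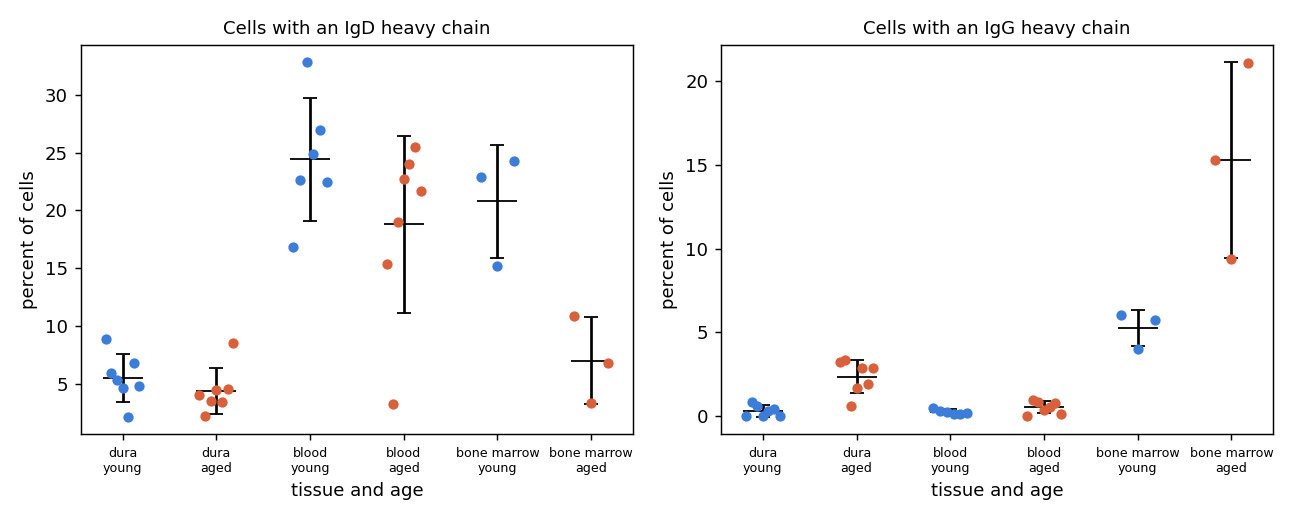
Percent of cells whose heavy chain was assigned to IgD (left) or IgG (right), by tissue and age; each point is 1 sample, the horizontal bar is the mean and the error bar the SD. Mean IgD was 5.51 in young and 4.41 in aged dura, against 24.4 and 18.8 in blood.

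IgG, a class made after switching, was 2.36% ± 1.01 (SD, n = 7) of aged dura cells and 0.527% ± 0.363 (SD, n = 7) of aged blood cells, with 6 of 7 dura samples above every blood sample (exact permutation p = 0.00233, adjusted p = 0.0163). In dura of mouse 5, 21 IgG3 cells belonged to 1 clone, whose heavy chain also occurred in dura of aged mice 4 and 6. Without this clone that sample would not lie above every blood sample (highest 0.963%). It counts among the switched cells as well. All switched classes together were 2.96% ± 1.05 in aged dura and 0.839% ± 0.479 in aged blood (exact permutation p = 0.00117, adjusted p = 0.0186), a difference of 2.36 percentage points in the mice numbered 1 to 3 and 1.93 in those numbered 4 to 7. In young mice the switched share was 0.964% ± 1.57 in dura and 1.25% ± 0.824 in blood (exact permutation p = 0.727, adjusted p = 0.895). CDR3, the heavy chain loop that contributes most to antigen contact, had a mean length of 12 ± 0.0568 amino acids in young dura clones and 12.1 ± 0.0543 in young blood clones. The CDR3 difference was -0.174 amino acids in young mice (exact permutation p = 0.000583, adjusted p = 0.0186) and -0.16 in aged mice (exact permutation p = 0.0117, adjusted p = 0.0414). In young mice the CDR3 difference was -0.169 in the mice numbered 1 to 3 and -0.176 in those numbered 4 to 7 (exact permutation p = 0.0571 in the latter), and in aged mice it was -0.193 and -0.136 (exact permutation p = 0.0857 in the latter).

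Few V genes were called between dura and blood. IGHV4-1 (chromosome 12, 113948284 to 113948577, GRCm38) made up 1.91% ± 0.403 of young dura clones and 0.829% ± 0.115 of young blood clones (log2 fold change 1.12, SE 0.28, edgeR adjusted p = 0.00242), and was the only V gene called of 39, with DESeq2 calling 1 as well. With no filter on low counts IGHV4-1 had an edgeR adjusted p = 0.0807, and the 1 gene then called was another. In aged mice edgeR called 0 of 39 V genes, with 3 at an unadjusted p under 0.05, and DESeq2 called 0. IGHV1-72 came closest, with 1.83% ± 1.15 of aged dura clones and 3.2% ± 0.434 of aged blood clones (log2 fold change -0.56, SE 0.18, edgeR adjusted p = 0.051). The V genes associated with B-1 cells, a self-renewing lineage, together made up 4.85% ± 2.11 of young dura clones and 4.58% ± 0.362 of young blood clones (exact permutation p = 0.791, adjusted p = 0.861), and 5.83% ± 1.1 and 5.37% ± 1.1 in aged mice (exact permutation p = 0.442, adjusted p = 0.677). In aged mice their difference was -0.69 percentage points in the mice numbered 1 to 3 and 1.32 in those numbered 4 to 7 (exact permutation p = 0.0286 in the latter, the smallest possible). Among them IGHV6-6 and IGHV1-55 had enough clones for edgeR, and neither passed in any of the 7 comparisons. IGHJ2 and IGHJ3 passed in 0 and 0 of 7 comparisons of any kind (lowest exact permutation p = 0.0956 and 0.275). The IGHJ2 difference between dura ages was -0.966 percentage points in the mice numbered 1 to 3 and 5.29 in those numbered 4 to 7, and that between aged dura and blood was 0.0279 and 3.54 (exact permutation p = 0.0286 for both in mice numbered 4 to 7, unadjusted). None of the 7 gene lists passed the correction between dura and blood at either age. In aged mice 2 had an unadjusted exact permutation p under 0.05. These were IGHJ4, at 20% ± 3.97 of dura and 24.9% ± 0.875 of blood clones, and IGHV1 with IGHV8, at 59.7% ± 2.64 and 62.4% ± 1.17.

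The second comparison set aged against young dura. IgG was 2.36% ± 1.01 (SD, n = 7) of aged and 0.311% ± 0.334 (SD, n = 7) of young dura cells, with 6 of 7 aged samples above every young sample (exact permutation p = 0.00175, adjusted p = 0.0163). Young dura held only 3 IGHG2B, 1 IGHG2C and 1 IGHG3 cells. In aged mouse 5, IgG was 2.87% and IgG3 2.43% of cells, with 21 IgG3 cells in 1 IGHV1-39 clone, singled out after the data were seen. The heavy chain of this clone also appeared in 4 dura cells of aged mouse 4 and 1 of aged mouse 6, mainly as IGHG2B. Without this clone mouse 5 would not lie above every young sample (highest 0.847%). Leaving out 1 whole sample at a time gave differences of 1.89 to 2.35 percentage points. IGHJ4, the J gene farthest from the V genes, fell from 26.9% ± 2.08 to 20% ± 3.97 of clones (exact permutation p = 0.00233, adjusted p = 0.0381). The V families IGHV2 and IGHV5, which lie nearest to the D segments, rose from 10.8% ± 2.29 to 14.1% ± 0.94 of clones (exact permutation p = 0.00233, adjusted p = 0.0381). The IgG difference was 1.91 percentage points in the mice numbered 1 to 3 and 2.16 in those numbered 4 to 7, that of IGHJ4 was -6.55 and -7.17, and that of IGHV2 and IGHV5 was 5.27 and 1.89 (exact permutation p = 0.0857 in the latter). The distal families IGHV1 and IGHV8 were at 59.7% ± 2.64 in aged and 63.9% ± 3.58 in young dura and did not pass (exact permutation p = 0.0355, adjusted p = 0.194), with differences of -5.66 and -3.03 in the 2 sets of mice (exact permutation p = 0.143 in the latter). The switched share was 2.96% ± 1.05 in aged and 0.964% ± 1.57 in young dura and did not pass either (exact permutation p = 0.0216, adjusted p = 0.069), with differences of 1.09 and 2.67 in the 2 sets. Without heavy chains that recurred in another mouse, a setting chosen after the data were seen, the switched difference was 1.63 (exact permutation p = 0.0589). edgeR called 0 of 39 V genes, with 4 at an unadjusted p under 0.05, and DESeq2 called 0.

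Cells in clones of 2 or more, a measure of expansion, made up 8.3% ± 5.35 (SD, n = 6) of aged and 2.03% ± 4.32 (SD, n = 7) of young dura cells at 119 cells per sample, which did not pass the correction (exact permutation p = 0.0455, adjusted p = 0.112). The mean V mutation was 0.252% ± 0.206 of bases in aged and 0.0621% ± 0.0524 in young dura and did not pass (exact permutation p = 0.0344, adjusted p = 0.0917). The expansion difference was 2.92 percentage points in the mice numbered 1 to 3 and 8.49 in those numbered 4 to 7, and the V mutation difference was 0.128 and 0.236. With each clone counted once the V mutation difference was 0.0853 (exact permutation p = 0.0536), against 0.19 over cells. With at least 3 UMIs the expansion difference was 9.69 (exact permutation p = 0.00216). Without heavy chains that recurred in another mouse the expansion difference was 0.928 (exact permutation p = 0.706), and with such chains kept in the mouse with most of their cells it was 6.09 (exact permutation p = 0.0554). These 2 settings were chosen after the data were seen, the second because the first also removed clones from the mouse that held most of them.

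**Figure D2:**
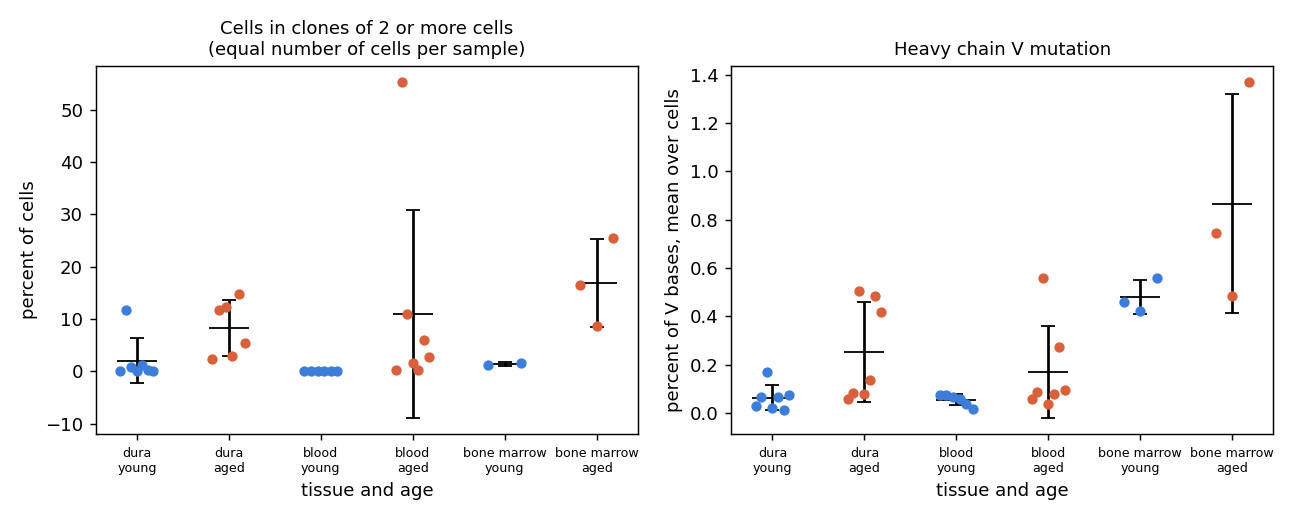
Percent of cells in clones of 2 or more cells at 119 cells per sample (left) and mean percent of V bases differing from germline (right), by tissue and age; points are samples, horizontal bars are means and error bars SD. In the left panel 1 aged blood sample stands at 55.2 percent.

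The largest clone exceeded 5% of cells in 3 aged dura samples. It used IGHV1-53 in mouse 3, with 53 of 685 cells (7.74%, 95% Wilson interval 5.96 to 9.98), IGHV1-12 in mouse 4, with 55 of 599 cells (9.18%, 95% Wilson interval 7.12 to 11.8), and IGHV1-72 in mouse 6, with 49 of 722 cells (6.79%, 95% Wilson interval 5.17 to 8.86). IgM was the main class of each, and the blood of these mice held 162, 52 and 89 cells of the same clones. The same heavy chains also appeared outside these mice, IGHV1-53 in 1 dura cell of young mouse 3, IGHV1-12 in 2 dura cells of aged mouse 5 and 1 of aged mouse 6, and IGHV1-72 in 4 dura cells and 1 blood cell of aged mouse 7. In aged blood the largest clone of mouse 2 used IGHV1-52 and IgM, with 646 of 2079 cells (31.1%, 95% Wilson interval 29.1 to 33.1), and that of mouse 3 was its IGHV1-53 dura clone, with 162 of 2742 cells (5.91%, 95% Wilson interval 5.09 to 6.85). In aged bone marrow of mouse 3 an IGHG2B clone with IGHV1-26 took 34 of 460 cells (7.39%, 95% Wilson interval 5.34 to 10.2).

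Clones were next compared between dura and blood of the same mouse. In aged mice 8.79% ± 6.19 (SD, n = 7) of dura cells belonged to a clone also found in blood, and in young mice 0.617% ± 1.05 (SD, n = 6), with 5 of 7 aged mice above every young mouse (exact permutation p = 0.0111, adjusted p = 0.0414). The 354 shared cells of aged dura fell into 65 clones, and 344 of them were IgM or IgD. Of the aged dura cells in clones of 2 or more, 72.1% were in a clone shared with blood, 316 of 438 cells over all mice. Per mouse this share ranged from 0% in mouse 1 and 8.7% in mouse 5 to 100% in mouse 2, and mice 3, 4 and 6 held most of these cells. The sharing difference was 6.61 percentage points in the mice numbered 1 to 3 and 9.49 in those numbered 4 to 7 (exact permutation p = 0.0571 in the latter). With each dura clone counted once the difference was 1.86 (exact permutation p = 0.0134), and without heavy chains that recurred in another mouse, a setting chosen after the data were seen, it was 3.7 (exact permutation p = 0.0146). In 4 of 6 young mice no shared clone was seen, which allows shares of up to 2.4%, 1.27%, 0.636% and 0.398%, taking 3 cells of those sampled as the limit of a count of 0. Of these, mouse 7 had an identical heavy chain in its own blood for 0.133% of dura cells, under another clone name. As background, 8.03% of aged dura cells had an identical heavy chain in their own blood and 0.642% in blood of other aged mice (exact sign-flip permutation p = 0.0156, the smallest 7 mice allow).

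**Figure D3:**
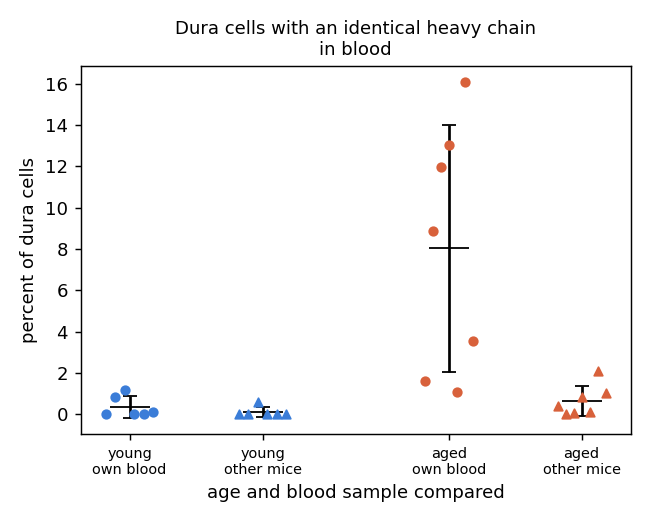
Percent of dura cells whose V gene, J gene and CDR3 nucleotides were found in blood of the same mouse (circles) or, as a mean, in blood of the other mice of that age (triangles); each point is 1 mouse, horizontal bars are means and error bars SD. The aged means were 8.03 in own and 0.642 in other blood.

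Aged blood was compared with young blood in the same way. IGHJ4 fell from 26.7% ± 0.757 to 24.9% ± 0.875 of clones (exact permutation p = 0.00233, adjusted p = 0.0381), and IGHJ1, at the other end of the J genes, rose from 17.5% ± 1.02 to 19.7% ± 0.935 (exact permutation p = 0.00408, adjusted p = 0.04997). The IGHJ4 difference was -2.07 percentage points in the mice numbered 1 to 3 and -1.52 in those numbered 4 to 7 (exact permutation p = 0.0571 in the latter), and that of IGHJ1 was 3 and 1.44. IGHV4-1 (log2 fold change 0.48, SE 0.15, edgeR adjusted p = 0.0388) and IGHV5-4 (chromosome 12, 113597448 to 113597741, GRCm38; log2 fold change 0.42, SE 0.14, edgeR adjusted p = 0.0388) were called. DESeq2 called 0 genes there, edgeR with library sizes alone called 0, and edgeR with only the blood groups fitted called 6, IGHV4-1 and IGHV5-4 among them. In the main fit 4 genes had an unadjusted edgeR p under 0.05. With 1 sample left out, 0 genes were called without aged mice 2, 3, 6 or 7 or young mice 1, 2, 6 or 7, and 1, another gene, without young mice 3 or 4. Cells in clones of 2 or more made up 11% ± 19.9 of aged and 0.0462% ± 0.0295 of young blood cells, with all 7 aged samples above every young sample (exact permutation p = 0.0705, adjusted p = 0.15). Without aged mouse 2 this difference went from 11 to 3.62 and passed without correction (exact permutation p = 0.00216, the smallest these samples allow). In mice numbered 1 to 3 it was 22.1 and in those numbered 4 to 7 it was 2.61 (exact permutation p = 0.0857 in the latter). Without thinning it was 13 (exact permutation p = 0.0216). IgA, the class of mucosal antibody, was 0.312% ± 0.32 in aged and 0.991% ± 0.7 in young blood and did not pass (exact permutation p = 0.0449, adjusted p = 0.0897). The IgA difference was -1.5 percentage points in the mice numbered 1 to 3 and 0.0918 in those numbered 4 to 7, and permuting within these sets gave an exact permutation p = 0.0557.

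Bone marrow differed from dura in its switched cells. The switched share was 26.7% ± 9.06 (SD, n = 3) in young and 19.2% ± 7.31 (SD, n = 3) in aged bone marrow, against 0.964% and 2.96% in dura (exact permutation p = 0.00833, adjusted p = 0.0414 at each age, where no smaller exact p is possible). IgA made up 21.5% ± 8.82 of young and 3.9% ± 3.9 of aged bone marrow cells, and IgG 5.25% ± 1.09 and 15.3% ± 5.85; 3 mice against 3 allow no exact permutation p under 0.1, the value both reached. V mutation was 0.48% ± 0.0715 in young bone marrow and 0.0621% ± 0.0524 in young dura (exact permutation p = 0.00833, adjusted p = 0.0414), and in IgM and IgD cells alone the difference was -0.00872 (exact permutation p = 0.808). CDR3 differed by -0.269 amino acids between young dura and bone marrow (exact permutation p = 0.00833, adjusted p = 0.0414), and IgD by -15.3 percentage points (exact permutation p = 0.00833, adjusted p = 0.0179). In aged mice none of these 3 passed. V mutation differed by -0.614 (exact permutation p = 0.025, adjusted p = 0.0727), or -0.363 without bone marrow of aged mouse 3. CDR3 differed by -0.259 (exact permutation p = 0.05, adjusted p = 0.114), or -0.0916 without bone marrow of aged mouse 2, and IgD by -2.62 (exact permutation p = 0.167, adjusted p = 0.211). With 1 sample left out at a time the aged IgD difference ranged from -4.45 to -0.679. IgA differed by -20.8 (exact permutation p = 0.00833, adjusted p = 0.0179) in young and -3.31 (exact permutation p = 0.00833, adjusted p = 0.0179) in aged mice, the latter -1.07 without bone marrow of aged mouse 1. With at least 3 UMIs per heavy chain the young differences were -51.8 percentage points for the switched share, -45.7 for IgA and -0.783 for V mutation. With each clone counted once the aged switched difference was -8.92 against -16.2. With at least 3 UMIs the young CDR3 and IgD differences no longer passed, at 0.0188 (exact permutation p = 0.808) and -0.993 (exact permutation p = 0.533). Bone marrow was sampled only in mice numbered 1 to 3 but was set against dura of mice 1 to 7. Tissue is thus partly mixed with the set of numbers, and mice 1 to 3 alone allow no exact p under 0.05. For V genes edgeR called 0 in young and 0 in aged mice, with 4 and 7 at an unadjusted p under 0.05, and DESeq2 called 1 and 1. Between bone marrow ages edgeR called 0, with 3 at an unadjusted p under 0.05, and DESeq2 called 0.

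Whether age acted differently on dura and blood was tested on the difference between the tissues within each mouse. For the switched share, dura minus blood was 2.12 ± 1.3 percentage points in aged mice (SD, n = 7) and -0.178 ± 1.39 in young mice (SD, n = 6), a difference of 2.3 (exact permutation p = 0.0117, adjusted p = 0.0414). For cells in clones of 2 or more the difference was 2.54 (exact permutation p = 0.277, adjusted p = 0.387), and for V mutation it was 0.0754 (exact permutation p = 0.257, adjusted p = 0.387). Without young mouse 2 the difference in expansion was 4.46 (exact permutation p = 0.0152). With mice kept as a block, cells in such clones were 4.64 percentage points more frequent in aged dura than in aged blood (exact sign-flip permutation p = 0.0312), against -2.73 over all samples (exact permutation p = 0.962, adjusted p = 1). The block left out mouse 2, whose dura sample had under 100 cells. Without blood of mouse 2 and with no block the difference was 4.64 as well (exact permutation p = 0.108), so the sign rested on that sample.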

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

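All tests of explanations in this part were chosen after the results were seen. Of 62 groups of samples searched for a sample far from the rest, 9 held one, and chance gives about 3.1.

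Young dura of mouse 2, with 119 cells, stood above the other samples for switched cells (4.24%, others up to 1.78%), cells in clones of 2 or more (11.8%, 14 cells, others up to 1.31%) and IgA (3.39%, others up to 1.18%). All young dura samples together held 6 IgA cells, so the switched and IgA values rest on few cells, mostly the same ones. Aged blood of mouse 2 stood above the others for cells in clones of 2 or more (55.2%, others up to 11%) and B-1-associated V genes (7.69% of clones), while its dura was lowest for the latter (3.45% of only 87 clones). Young dura of mouse 3 was highest for V mutation (0.167%), aged dura of mouse 7 was highest for IgD (8.5%) and young dura of mouse 1 was lowest for IGHJ4 (22.4%). The age effect on the switched share differed between dura and blood by 2.3 percentage points.

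IgD was lower in dura than in blood at both ages, and its share depended on depth, at 58.6% of young blood cells with 1 UMI and 1.99% of those with 9 or more. Over 5 UMI bins of equal weight the difference was -17 percentage points in young mice (exact permutation p = 0.00466) and -23 in aged mice (exact permutation p = 0.000583), which argues against UMI depth as the whole cause. Bins of young dura held as few as 4 cells and young dura of mouse 1, at 33%, lay above every young blood sample (-20.6 without it). With each clone counted once it was -18.9 and -15.7, which argues against expanded clones as the whole cause. A larger share of immature B cells in dura, a difference between tissues, and the assignment of 1 class to cells making both IgM and IgD stay open and untested.

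Clones of aged dura were found in blood of the same mouse, and the largest blood clone took a larger share of dura than of blood, with Wilson intervals apart, in 2 of 7 aged mice (4 and 6). In mouse 2 it took a smaller share of dura, also with intervals apart (1.11% against 31.1% of blood, 1 of 90 dura cells). If blood left in the dura kept its IgD share, that share bounds it, at up to 29.5% of dura cells in mouse 3, and in 3 mice (3, 4 and 6) the clone lay above what such blood could bring (2.03% against 7.74% in mouse 3), which argues against it as the whole cause there. Shared dura cells had a median of 2 times the UMIs of other dura cells (0.786 to 3.33 over mice), but cells with a mutated chain of another mouse had a median of 1.67 times their sample's median UMIs, so UMIs do not tell carried RNA apart. The chance that 1 dura and 1 blood cell share a clone was 0.306 percentage points higher in aged mice (exact permutation p = 0.039), which argues against the number of cells sampled as the whole cause. Blood left in the dura may account for sharing in mice 1, 2, 5 and 7, and RNA carried between libraries and age stay open.

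Identical heavy chains in different mice numbered 67 of 49462. They had a median of 3 N bases against 7 in the rest, 4 fewer, consistent with independent formation of simple rearrangements. In 7 mutated heavy chains found in a second mouse, a median of 100% of V mutations in the second mouse were also carried in the first (lowest 8.33%). Mutations of the first mouse were pooled over its 1 to 194 cells with the chain, so a single cell need not carry all of them. The match argues against independent formation of most of these chains, and all 7 recurred within 1 set of numbers. Clones of 10 or more cells recurred 5.19 percentage points more often in mice of their own set than of the other (exact sign-flip permutation p = 0.125). This test alone does not tell transfer between libraries from chance, and the test on mutated chains was added after it. There, 1 IGHV1-39 cell of aged mouse 7 carried 10 V mutations, all found in aged mouse 6. In young mouse 3, 1 IGHV1-53 cell carried 8, all found in aged mouse 3. Such shared sets argue against chance for most of these chains, with 1 or 2 cells per second mouse. The same cell barcode and junction were found together in 2 samples in 0 cases. That argues against reads carried between libraries with their barcode, unless such cases were removed earlier. Transfer of RNA between libraries without its barcode stays open for these chains.

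For counts of V genes, 2 were called between blood ages. Of 100 splits drawn from 1716, 2 called as many, the real one included (highest other 2). These splits ignored the 2 sets of numbers, and with the set as a term 1 gene was called, with DESeq2 or library sizes alone 0. Neither gene was kept in 10 of 13 fits with 1 sample left out, so the calls are uncertain and chance is not excluded. Between young dura and blood 1 gene was called. Of 64 splits that part every pair, 2 called as many, the real one included (highest other 1). Chance is not excluded there either, and with no filter on low counts the call of IGHV4-1 was lost (edgeR adjusted p = 0.0807). With 0 genes called, every split calls as many, so splits decide nothing between dura ages (100 of 100, highest other 1) or between aged dura and blood (64 of 64, highest other 1). The same holds, with too few splits besides, between bone marrow ages (0 called; 10 splits, highest other 1) and between dura and bone marrow (0 called at each age; 8 splits, highest other 0 in young and 1 in aged mice).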

How the results depend on the processing

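Results were judged here by the unadjusted exact permutation p, and V genes by the adjusted p of each tool. Where a p under 0.05 was possible, direction and side of the threshold were kept by 602 of 703 differences under other settings and 1060 of 1155 with 1 sample left out. Counts stayed within 1.5 times in 48 of 69 and 123 of 154. Where no such p was possible, 16 of 133 and 8 of 87 differences turned sign. The settings with 5 or more UMIs, those on heavy chains recurring between mice, and for sharing those on UMIs and sets of numbers were chosen after the data were seen. Settings on light chains and on cells with several heavy chains, and light chain lists, were not run, as the table used holds 1 heavy chain per cell. The mouse as a replicate block, judged by unadjusted p, changed 1 call, given here, and no other. Its 6 young and 7 aged dura and blood pairs allow no exact sign-flip p under 0.0312 and 0.0156, so smaller p came from free permutation alone. Bone marrow pairs, 2 or 3, allow no p under 0.05, nor do mice numbered 1 to 3 alone. Sets of numbers and UMI minimums leave fewer samples or cells; otherwise the cause was not tested. Low cell numbers limit bone marrow and the smallest dura samples.

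Differences are written as tissue by age (aged minus young) or as dura-blood and dura-marrow (dura minus the other), and lists passing counts gene lists with an unadjusted p under 0.05. With heavy chains found in 1 mouse alone, the sign turned for CDR3 length in blood by age (0.000277), CDR3 length in marrow by age (-0.0053), and p no longer passed for switched share in dura by age (1.63), clones of 2 or more in dura by age (0.928), and p newly passed for clones of 2 or more in aged dura-marrow (-13.1). In mice numbered 1 to 3, the sign turned for switched share in young dura-blood (0.0308), V mutation in aged dura-blood (-0.0181), CDR3 length in dura by age (-0.0518), IgM share in dura by age (2.35), distal VH in young dura-blood (-0.104), B-1-associated VH in young dura-blood (-0.353), B-1-associated VH in aged dura-blood (-0.69), IGHJ2 in dura by age (-0.966), IGHJ2 in young dura-blood (1.32), IGHJ4 in young dura-blood (-1.07), and the value moved for switched share in blood by age (-1.24), IgD share in dura by age (-3.44), IgA share in blood by age (-1.5), D-proximal VH in aged dura-blood (1.97). In mice numbered 4 to 7, the sign turned for switched share in blood by age (0.393), clones of 2 or more in aged dura-blood (6.22), CDR3 length in blood by age (0.0202), IgD share in dura by age (0.647), IgA share in dura by age (0.511), IgA share in blood by age (0.0918), D-proximal VH in aged dura-blood (-0.582), IGHJ1 in young dura-blood (-1.14), IGHJ3 in dura by age (-1.27), IGHJ3 in blood by age (0.0643), IGHJ3 in young dura-blood (1.6), and p no longer passed for CDR3 length in young dura-blood (-0.176), CDR3 length in aged dura-blood (-0.136), D-proximal VH in dura by age (1.89), distal VH in dura by age (-3.03), distal VH in aged dura-blood (-2), IGHJ4 in blood by age (-1.52), clone sharing by age (9.49), and p newly passed for IgA share in young dura-blood (-0.374), B-1-associated VH in aged dura-blood (1.32), IGHJ2 in dura by age (5.29), IGHJ2 in aged dura-blood (3.54), and counts became lists passing in blood by age (1). With at least 3 UMIs, the sign turned for clones of 2 or more in young dura-marrow (-3.78), V mutation in young dura-blood (-0.0179), CDR3 length in blood by age (0.0147), CDR3 length in young dura-marrow (0.0188), IgG share in young dura-blood (-0.132), B-1-associated VH in young dura-marrow (-0.436), B-1-associated VH in aged dura-marrow (-0.338), IGHJ3 in aged dura-marrow (-0.147), IGHJ2 in marrow by age (-0.577), and p no longer passed for IgD share in young dura-marrow (-0.993), D-proximal VH in young dura-marrow (-0.841), D-proximal VH in aged dura-marrow (-2.42), distal VH in dura by age (-3.02), distal VH in aged dura-blood (-2.05), and p newly passed for clones of 2 or more in aged dura-marrow (-17.7), and the value moved for switched share in marrow by age (-27.1), IgD share in marrow by age (-1.64), IgA share in marrow by age (-41), and counts became lists passing in aged dura-blood (1), lists passing in aged dura-marrow (0), lists passing in young dura-marrow (0). With recurring heavy chains kept in the mouse with most cells, p no longer passed for clones of 2 or more in dura by age (6.09). With clones of identical V, J and CDR3 nucleotides, p no longer passed for clones of 2 or more in dura by age (5.38), and p newly passed for clones of 2 or more in young dura-blood (2.58). With permutation within the 2 sets of numbers, p no longer passed for clones of 2 or more in dura by age (6.27), IgA share in blood by age (-0.679). Without thinning, the sign turned for clones of 2 or more in young dura-marrow (-1.58), and p newly passed for clones of 2 or more in blood by age (13). At 2 times the depth, the sign turned for clones of 2 or more in young dura-marrow (-1.8), and p newly passed for clones of 2 or more in young dura-blood (0.842), clones of 2 or more in aged dura-marrow (-14.7). With mice as a block, the sign turned for clones of 2 or more in aged dura-blood (4.64), B-1-associated VH in young dura-marrow (-0.348), IGHJ1 in aged dura-marrow (0.915). Aged dura-blood there left out mouse 2, and without its blood sample and with no block it was the same 4.64 (exact permutation p = 0.108). With the chance that 2 cells share a clone, the sign turned for clones of 2 or more in young dura-marrow (-0.0176). In IgM and IgD cells alone, p no longer passed for V mutation in dura by age (0.161), V mutation in young dura-marrow (-0.00872), V mutation in aged dura-marrow (-0.11). With each clone counted once, the sign turned for V mutation in marrow by age (-0.0257), and p no longer passed for V mutation in dura by age (0.0853). With 5 or more UMIs, the sign turned for IgD share in young dura-marrow (0.17), IgD share in aged dura-marrow (0.337), and the value moved for IgD share in marrow by age (-0.721). Without pairing of mice, the sign turned for age effect difference for clones of 2 or more (-4.71), as aged blood of mouse 2 came back in, and with that mouse left out of both tissues, a setting chosen after the data were seen, it was 2.66. With cells instead of clones, the sign turned for IGHV1-72 in dura by age (0.11), IGHV6-6 in blood by age (-0.018), IGHV6-6 in young dura-blood (-0.014), IGHV1-55 in aged dura-blood (-0.15), and p no longer passed for IGHV4-1 in blood by age (0.50), IGHV5-4 in blood by age (0.35), and p newly passed for IGHV1-52 in aged dura-blood (-3.68), IGHV5-6 in young dura-marrow (-1.96), and counts became V genes called in blood by age (1), V genes called in aged dura-blood (2), V genes called in young dura-marrow (1), V genes called in aged dura-marrow (1). With library sizes alone, the sign turned for IGHV6-6 in blood by age (-0.00038), IGHV1-55 in marrow by age (-0.20), and p no longer passed for IGHV4-1 in blood by age (0.45), IGHV5-4 in blood by age (0.38), and p newly passed for IGHV5-6 in young dura-marrow (-1.93), IGHV1-19 in aged dura-marrow (-1.27), and counts became V genes called in blood by age (0), V genes called in young dura-marrow (1), V genes called in aged dura-marrow (1). With no filter on low counts, the sign turned for IGHV6-6 in blood by age (-0.028), IGHV1-55 in marrow by age (-0.19), IGHV6-6 in young dura-blood (-0.18), IGHV1-55 in young dura-blood (-0.14), and p no longer passed for IGHV4-1 in blood by age (0.42), IGHV5-4 in blood by age (0.36), IGHV4-1 in young dura-blood (0.88), and p newly passed for IGHV1-19 in blood by age (-0.45), IGHV1-80 in young dura-blood (-0.95), IGHV1-72 in aged dura-blood (-0.65), and counts became V genes called in aged dura-blood (1). With the set of numbers as a term, the sign turned for IGHV1-55 in marrow by age (-0.00071), and p no longer passed for IGHV5-4 in blood by age (0.35), and counts became V genes called in blood by age (1). In IgM and IgD clones alone, the sign turned for IGHV6-6 in blood by age (-0.013), IGHV1-55 in marrow by age (-0.048), IGHV1-55 in young dura-marrow (-0.0031), and p no longer passed for IGHV4-1 in blood by age (0.42), IGHV5-4 in blood by age (0.36), and p newly passed for IGHV1-19 in blood by age (-0.45), IGHV1-19 in aged dura-marrow (-1.35), and counts became V genes called in blood by age (1), V genes called in aged dura-marrow (1). With DESeq2, the sign turned for IGHV1-55 in marrow by age (-0.20), IGHV1-55 in young dura-marrow (-0.029), and p no longer passed for IGHV4-1 in blood by age (0.52), IGHV5-4 in blood by age (0.43), and p newly passed for IGHV5-6 in young dura-marrow (-2.01), IGHV1-19 in aged dura-marrow (-1.29), and counts became V genes called in blood by age (0), V genes called in young dura-marrow (1), V genes called in aged dura-marrow (1). With only the compared groups fitted, the sign turned for IGHV6-6 in young dura-blood (-0.0083), and p newly passed for IGHV1-19 in blood by age (-0.42), IGHV1-72 in aged dura-blood (-0.55), IGHV1-19 in aged dura-marrow (-1.35), and counts became V genes called in blood by age (6), V genes called in aged dura-blood (1), V genes called in aged dura-marrow (1).

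Values here are ranges over leaving out 1 sample at a time. The ranges were clones of 2 or more in dura by age 4.96 to 7.9, clones of 2 or more in blood by age 3.62 to 12.8, clones of 2 or more in young dura-blood 0.362 to 2.32, clones of 2 or more in aged dura-blood -4.52 to 4.64, clones of 2 or more in young dura-marrow -1.03 to 0.928, clones of 2 or more in aged dura-marrow -12.6 to -4.21, V mutation in dura by age 0.148 to 0.222, V mutation in blood by age 0.0503 to 0.137, V mutation in young dura-blood -0.00912 to 0.0165. Others were V mutation in aged dura-marrow -0.805 to -0.363, CDR3 length in dura by age -0.0101 to 0.033, CDR3 length in blood by age -0.0204 to 0.0205, CDR3 length in aged dura-marrow -0.374 to -0.0916, IgA share in dura by age -0.17 to 0.395, IgG share in young dura-blood -0.0387 to 0.103, distal VH in young dura-blood -0.343 to 1.24, distal VH in young dura-marrow -3.67 to 2.16, B-1-associated VH in young dura-blood -0.197 to 0.925. Further ranges were B-1-associated VH in young dura-marrow -0.591 to 0.943, IGHJ1 in young dura-marrow -0.257 to 2.44, IGHJ2 in blood by age -0.131 to 0.438, IGHJ2 in young dura-marrow -0.0245 to 3.16, IGHJ3 in young dura-marrow -8.68 to 0.601, IGHJ3 in aged dura-marrow -0.376 to 2.24, IGHJ4 in young dura-blood -0.00265 to 0.996, IGHJ4 in young dura-marrow -0.319 to 3.07, age effect difference for clones of 2 or more 1.31 to 4.46. Then came lists passing in aged dura-blood 1 to 3, lists passing in young dura-blood 0 to 1, lists passing in aged dura-marrow 1 to 2, lists passing in young dura-marrow 0 to 1, V genes called in blood by age 0 to 3, V genes called in young dura-blood 1 to 2, V genes called in aged dura-blood 0 to 1, V genes called in young dura-marrow 0 to 1, V genes called in aged dura-marrow 0 to 2. The ranges were B-1-associated VH in marrow by age -0.0308 to 1.47, D-proximal VH in marrow by age -0.183 to 3.64, IGHJ2 in marrow by age -0.233 to 2.96, IGHJ3 in marrow by age -7.87 to 1.41, CDR3 length in marrow by age -0.165 to 0.117, age effect difference for V mutation 0.0357 to 0.0982.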

Other observations

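The values in this part were picked out after the data were seen. The 285 IgA cells of young blood had a median of 279 UMIs and a mean V mutation of 2.12%, while the 18140 IgM cells had 6 UMIs and 0.0324%. Median UMIs of IgA cells were 413 in aged dura (23 cells), 29 in young dura (6 cells), 29 in aged blood, 36.5 in young and 9 in aged bone marrow, where IGHG2B cells had 21. Mean V mutation in aged blood was 3.89% in IgA, 1.92% in IGHG2B (57 cells), 3.34% in IGHG1 (12 cells), 3.79% in IGHG2C (27 cells) and 4.68% in IGHG3 (8 cells). An IgG3 clone with IGHV1-39 in aged dura of mouse 5, singled out after its values were seen, held 22 of 907 cells with a median of 1275 UMIs and a mean V mutation of 0%. Its heavy chain also appeared in 4 dura cells of aged mouse 4 and 1 of aged mouse 6.

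IGHV11-2, typical of B-1 cells that bind phosphatidylcholine, had 7 of 82 heavy chains in over 1 mouse, and 1 of them in 11 mice. IGHV12-3, of the same kind, had 5 of 58. Clones found in all 3 tissues numbered 11 in aged and 1 in young mice. Dura cells in a clone found in bone marrow of the same mouse were 2.43%, 6.67% and 13.6% in aged mice 1, 2 and 3, and 0%, 0% and 0.592% in young mice 1, 2 and 3, where a count of 0 allows up to 2.4% and 2.52%.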
